A study of Mus musculus with 2 samples.

How the data were processed

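Single-cell RNA-seq was measured in 2 libraries of mouse cells enriched for chondrocytes, taken from the epiphyses of limb long bones at 3 to 4 days of age and grown on plates. One library came from cells labelled as having no treatment and the other from cells labelled as treated with TNFa (tumour necrosis factor alpha, an inflammatory cytokine), so there was 1 library per group. The protocol text of both labels gives 2 hours without serum and TNFa overnight. Whether the untreated cells were also kept without serum is not separately stated. The unit is the UMI count per gene and cell. Per the submitters' processing notes, the deposited counts were made with Cell Ranger 7.0.1 on the mm10 genome. Each library's matrix was deposited in 2 identical copies, of which 1 was read. The files list 32285 genes.

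A barcode was kept as a cell with at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet as run by scanpy 1.11.5, at an expected rate of 0.06. Its automatic threshold marked 0 of 7775 untreated and 1 of 6259 TNFa cells, so few that the call is taken not to have worked. Whether doublets had been removed before deposit is not stated and was not tested. An alternative without the 6% of cells of highest score (518 untreated and 377 TNFa cells) was therefore added. Cells were scaled to 10000 counts, log transformed, and reduced to 2000 variable genes chosen within each library. Each gene was centred and scaled within its library. Clusters came from 30 principal components (scikit-learn 1.9.0), 20 nearest neighbours and Leiden at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9).

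Clusters were named from marker lists of 22 cell types fixed beforehand. A marker counted at 1.5-fold or more over the other cells of its library, with 20 CPM added, and in 10% or more of the cluster's cells. A name needed 4 markers and either a margin of 2 over any other type or 3 markers among the 10 leading genes of the cluster with none of another type. A type with more markers among those 10 genes than the named one, or as many unless both had 0, ruled the name out, as did a median UMI number under 0.333 of the library's with no marker among the 10. These naming thresholds were set after seeing the data, and clusters they left unnamed are called by number. Any difference from the names the submitters use may come from this rebuilt naming.

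With 1 library per group there is no test, so no p-value is given. Counts were summed over the kept cells of a library or class and scaled to a common total as CPM, with exact Poisson 95% intervals. Ratios of CPM, TNFa over untreated, have exact conditional binomial 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals. All intervals cover counting error only. Log2 ratios add 0.5 count to each sum. A ratio against 0 counts is a lower bound taken at a floor of 3 counts over the library or class. For 23 gene lists fixed beforehand, the median log2 ratio was taken over members with at least 20 UMIs. It was ranked among 10000 random lists of the same size, matched on mean CPM in 20 bins. Differences between classes in a log2 ratio have intervals from 10000 Poisson draws. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

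Genes were named by a rule set beforehand. Among genes at 50 CPM or more in a library, it took the 15 with the highest and the 15 with the lowest ratio, ranked by the interval bound nearest to 1. Mitochondrially encoded, ribosomal protein, unnamed and sex-linked genes were left out. Within each class of at least 100 cells per library it took 5 on each side at 100 CPM or more, and from each list up to 4 members at 20 CPM or more. A set of 26 genes, among them Col2a1, Acan, Mmp13 and Actb, was named whatever its values.

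The ratio and list steps were tested on simulated counts with 200 genes set to known folds, 50 per fold. These were Poisson counts drawn at the untreated levels. The test therefore checks the calculation and not spread between cells, libraries or cultures. For the whole-library comparison, run on 17557 genes, the interval held the true ratio for 95.5% of unchanged genes and for 94.0%, 94.0%, 94.0% and 96.0% of genes set to folds of 0.5, 1.25, 2 and 4. It excluded 1 for 96.0%, 74.0%, 100% and 100% of these. Of 200 lists of unchanged genes, 3.0% lay outside the central 95% of random lists, and a list of 2-fold genes stood at percentile 100. For the dividing cells, run on 11073 genes, the interval held the true ratio for 95.1% of unchanged genes and excluded 1 for 94.0%, 38.0%, 98.0% and 100% of genes at the same folds. There 4.5% of the unchanged lists lay outside.

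Before the data were examined, 21 other settings were chosen: other scalings, filters, depths, list rules and clusterings. A further 5 were added after the data were seen. These were the removal of cells of highest doublet score, from the ratios and from the shares, the removal of cluster 11, each class reduced to its main cluster, and cluster 10 counted as chondrocyte-like. A value was held to have moved when it differed from the main value by more than the half-width of its own counting interval, and to have changed direction when its sign turned and that interval had excluded 0. A first run had used a wider interval for lists, from resampling their members, and was replaced because it covers more than counting error. The results for which each move is given as a value were settled in the same step, after a first set of moves had been seen. They are 4 whole-library lists, the class shares, the NF-kB list in 2 classes and 4 list differences between these classes, and the other moves are given as counts. The rule for when the test of which cells carry each of the 15 highest genes counts as void was changed 3 times after its value had been seen, and its verdict changed with it, while the value did not.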

Results

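The data are UMI counts of single cells from 2 libraries of cultured mouse limb cells enriched for chondrocytes, 1 untreated and 1 treated with TNFa. The untreated library held 8120 barcodes and 133107152 UMIs, and the TNFa library 6496 barcodes and 130921806 UMIs. After filtering, 7775 untreated cells with a median of 15831 UMIs and 6258 TNFa cells with a median of 19968.5 UMIs remained. With 1 library in each group no value has a replicate check. Every interval below is a 95% interval of counting error only. Treatment and library cannot be separated, and the values compare these 2 libraries.

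The first comparison asks how the cells grown with TNFa differed from those grown without it, over all kept cells. Of the fixed gene lists, 17 of 20 chemokines, 21 of 21 inflammatory effectors and 24 of 24 interferon-response genes were at least 2-fold higher in the TNFa library, and 17 of 24 cartilage matrix genes were at least 2-fold lower. Ccl5, a chemokine for T cells and monocytes, was at 0.832 CPM (UMIs scaled to a common total) in the untreated and 41145 CPM (41110 to 41179) in the TNFa library, a ratio of 49429 (41011 to 60142). Saa3, an acute-phase protein, was at 7.17 and 14471 CPM, and Mmp3, a protease of cartilage matrix, at 1.23 and 2560 CPM. Acan, the core protein of aggrecan, was at 146 and 7.97 CPM, a ratio of 0.0545 (0.0511 to 0.0580). The main collagen of cartilage, Col2a1, was at 2906 and 1034 CPM, a ratio of 0.356 (0.354 to 0.358).

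The 15 genes with the highest ratio were Ccl5, Cxcl10, Nos2, Cxcl9, Saa3, Mmp3, Ccl20, Cxcl13, Ccl2, Gbp5, Cxcl2, Rsad2, H2-Q6, Il13ra2 and AW112010. Together they held 7.10% of the UMIs of the TNFa library and 0.002% of those of the untreated library. Nos2, the inducible nitric oxide synthase, had 1 UMI in the untreated library and 27159 in the TNFa library, a ratio of 27534 with an interval from 4941 to 1087590. The 15 genes with the lowest ratio were Ldb2, Gdf10, Lgr5, G0s2, Acan, Kcnd2, Fxyd6, Col27a1, Itgbl1, Map2, Ccn2, Omd, Lmcd1, Fry and Peg3. Lgr5, a receptor that strengthens WNT signalling, was at 106 and 5.30 CPM. Ccn2, a secreted matrix-associated growth factor, was at 206 and 18.6 CPM.

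**Figure D1:**
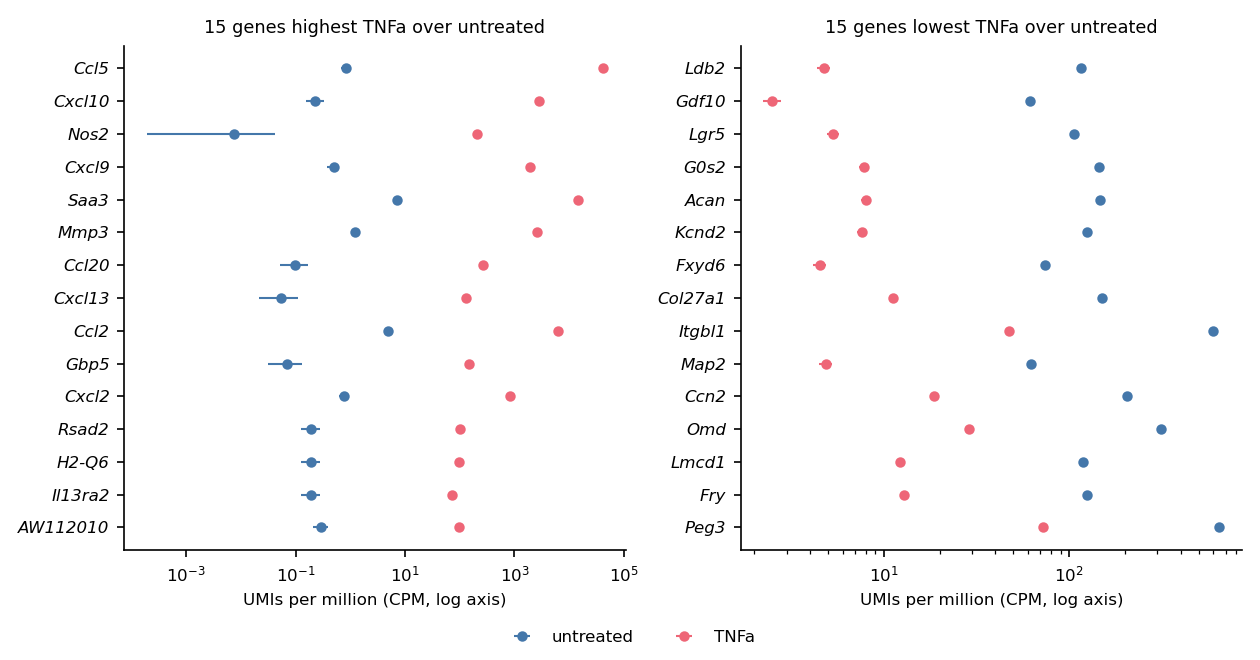
Level of each of the 15 highest and 15 lowest genes in the untreated and TNFa libraries, in CPM on a log axis, with exact Poisson 95% intervals as bars. Ccl5 stands at 0.832 and 41145 CPM and Acan at 146 and 7.97 CPM.

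Targets of NF-kB, the transcription factor that TNFa activates, were higher as a group. The list had a median log2 ratio of 2.84 (2.76 to 2.91), with 18 of 22 members at least 2-fold higher and 0 at least 2-fold lower. Its inhibitor Nfkbia was at 35.5 and 786 CPM, and Tnfaip3, which ends the signal, at 0.643 and 40.3 CPM. Icam1, an adhesion protein, was at 10.9 and 480 CPM, while Traf1 and Nfkbie had ratios of 47.9 and 36.4. Of 20 measured chemokines 17 were at least 2-fold higher, with a median of 5.72 (5.52 to 5.99). With 10 CPM added to both libraries, which shrinks the ratios of low genes, the NF-kB median was 1.86 and the chemokine median 2.48. Ccl2 was at 4.87 and 6131 CPM and Cxcl1 at 6.89 and 927 CPM. In the cytokine and growth factor list, 15 of 19 members were at least 2-fold higher, with a median of 3.09, or 0.48 with 10 CPM added. Csf1, a growth factor of macrophages, was at 136 and 608 CPM. Il6 was at 0.726 and 12.7 CPM and Tnf itself at 0.0908 and 2.27 CPM, with 65.2% of its UMIs in the TNFa library in 20 macrophage-like cells.

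All 24 measured interferon-response genes were at least 2-fold higher, with a median log2 ratio of 4.98 (4.94 to 5.06). Gbp2, an interferon-induced GTPase, was at 2.67 and 475 CPM. All 16 genes of MHC class I presentation were at least 2-fold higher, with a median of 3.26. Psmb8, a subunit of the immunoproteasome, was at 4.12 and 436 CPM and H2-K1 at 76.8 and 1763 CPM. Of 7 MHC class II genes 4 were at least 2-fold higher, with a median of 1.56, or 0.26 with 10 CPM added, 0.55 with classes weighted alike and 2.49 with members of 200 UMIs or more, and Cd74 was at 0.477 and 68.9 CPM. All 21 inflammatory effectors were at least 2-fold higher, with a median of 3.95 (3.85 to 4.04), or 2.20 with 10 CPM added. Among them Lcn2, an iron-scavenging protein, was at 17.3 and 2329 CPM, Cfb at 5.11 and 539 CPM, Sod2 at 87.3 and 1040 CPM and Ptgs2 at 5.89 and 49.5 CPM. The macrophage activation list, run as a check for another cell type, had 11 of 22 members at least 2-fold higher and a median of 0.98, or 0.17 with 10 CPM added and 0.54 as a mean of per-cell CPM. Its member Tlr2 was at 6.11 and 130 CPM.

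Genes of the cartilage matrix were lower as a group. The list median was -1.64 (-1.66 to -1.56), with 17 of 24 members at least 2-fold lower and 0 at least 2-fold higher. Matn3 was at 26.9 and 1.42 CPM and Hapln1, which links aggrecan to hyaluronan, at 176 and 23.2 CPM. Prg4, the lubricant of the joint surface, was the member with the highest ratio, 1.57 (1.51 to 1.64). Among regulators of chondrocytes, 9 of 19 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.94, or -0.54 with 10 CPM added. Sox9, the transcription factor that sets chondrocyte identity, was at 208 and 35.5 CPM. Bmpr1b, a BMP receptor, was at 53.3 and 223 CPM. In the hypertrophy and mineralization list, 7 of 13 were at least 2-fold lower, with a median of -1.32, or -0.14 with 10 CPM added. Col10a1 was at 4.21 and 2.89 CPM, whereas Mmp13 and Spp1 had ratios of 18.8 and 2.55. The TGFb, BMP and WNT list had 22 of 31 members at least 2-fold lower and a median of -1.21, or -0.80 with 10 CPM added. Id1, a target of BMP signalling, was at 351 and 42.1 CPM and the WNT inhibitor Dkk2 at 20.2 and 0.560 CPM. Bmp2 was at 3.72 and 24.7 CPM. The fibrous matrix list had a median of -0.50, with 5 of 23 at least 2-fold lower. Thbs1 was at 1469 and 266 CPM.

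Of the matrix proteases 8 of 23 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.38 (0.34 to 0.40), or 0.14 with 10 CPM added and 0.65 with trimmed means. Mmp13, a collagenase that cuts type II collagen, was at 25.9 and 488 CPM. Adamts5, an aggrecanase, was at 233 and 304 CPM, and Adamts12 at 33.2 and 7.16 CPM. The protease inhibitors went both ways, with 3 of 10 at least 2-fold higher, 3 at least 2-fold lower and a median of -0.03 (percentile 80.6). Their median was above 0 with ratios centred on the median gene (0.13) and with trimmed means (0.23). Timp1 was at 215 and 1559 CPM and Timp3 at 3042 and 1183 CPM. The lysyl oxidase and collagen processing list had a median of -0.02 (percentile 88.6), with Loxl2 at 27.7 and 46.5 CPM and P4ha2 at 77.1 and 317 CPM.

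Genes of glycolysis and hypoxia had a median of 1.59, with 19 of 22 at least 2-fold higher. The glycolytic enzyme Gapdh was at 540 and 1674 CPM, a ratio of 3.10, and Actb had a ratio of 1.31. The TNF receptor and death signalling list had a median of 0.49, or 0.23 with 10 CPM added, with 9 of 21 at least 2-fold higher. Casp4 was at 4.29 and 81.8 CPM and Mlkl, which carries out necroptosis, at 2.61 and 45.7 CPM. Tnfrsf1a, the main TNF receptor, was at 52.1 and 56.1 CPM and Tnfrsf1b at 5.49 and 23.2 CPM. Immediate early and heat shock genes had a median of -0.73, with 6 of 22 at least 2-fold lower. Fos was at 1181 and 378 CPM, and Ier3, an NF-kB target, at 79.7 and 472 CPM. The unfolded protein response list had a median of 0.17 (percentile 99.0) with 0 of 18 members beyond 2-fold. The S phase list had a median of -0.01 (percentile 98.4), or -0.12 both with cells thinned and with classes weighted alike and 0.26 with trimmed means, so that no direction is settled, and the G2 and M phase list of -0.50 (percentile 6.2), or -0.17 with 10 CPM added. Mki67, a marker of cycling cells, was at 14.6 and 8.12 CPM. The osteoclast list had a median of 0.11 (percentile 97.1), with Ckb at 70.8 and 11.1 CPM and Ctsk at 139 and 125 CPM, a log2 ratio of -0.15 that was above 0 under both other scalings.

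The lists on interferon response, chemokines, cytokines, NF-kB targets, inflammatory effectors, MHC class I, glycolysis and hypoxia, and TNF receptor and death signalling stood at percentile 100 of matched random lists, and so did macrophage activation, the check for another cell type. The macrophage activation list had a median of 1.60 within chondrocyte-like cells, over the 10 members also measured in fibroblast-like cells. Its percentile therefore does not tell macrophages from other cells. Cartilage matrix, TGFb, BMP and WNT, and immediate early and heat shock genes stood at percentile 0. The median gene at 50 CPM or more had a log2 ratio of -0.16, and centring on it adds 0.16 to every log2 ratio. Scaling by trimmed means adds 0.27 to each, so that values less than this below 0 have no settled direction.

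The second comparison asks which populations carried these differences, as the series title names differential effects on selected populations. Ccl5 and Cxcl10 were among the 5 genes with the highest ratio in each of the 8 classes or clusters with at least 100 cells per library, cluster 11 included. The NF-kB list median lay between 2.49 in cluster 10 and 3.02 in cluster 4, and was 2.09 in cluster 11, whose content differed between the libraries. Cartilage matrix medians lay between -2.13 in the fibroblast-like cells (-1.24 with each library clustered on its own) and -0.83 in cluster 3. If TNFa cluster 11 is taken as free RNA, an assumption, at most 4.23% to 6.83% of the UMIs of a TNFa class are free RNA. Col2a1 in TNFa fibroblast-like cells, at 43.6 CPM or 4.83% of its 903 CPM in cluster 11, sets that bound for them, so these medians do not show a difference within fibroblast-like cells themselves. Col2a1 in TNFa clusters 3 and 10 was at 1729 and 1973 CPM, above its level in cluster 11.

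Chondrocyte-like cells (1379 untreated, mostly cluster 6, and 1104 TNFa, mostly cluster 8) carried Col2a1, Acan and Sox9. Fibroblast-like cells (1428 untreated, mostly cluster 5, and 1205 TNFa, mostly cluster 7) carried Postn, Col14a1 and Clec3b. Their name rests on fewer markers, 5 of 12 in cluster 5 and 4 of 12 in cluster 7, with 0 among the 10 leading genes. Clusters 6 and 8 carried 15 and 13 of 15 chondrocyte markers. Dividing cell-like cells were cluster 12, with 203 and 184 cells. In cluster 1 the leading genes were Acta2, Tagln, Col1a1 and Scx, and in cluster 4 Pdzrn4, Eya1 and Matn4. Fgf14, Rcan2 and Timp3 led cluster 3, and Mmp13, Spp1, Runx2 and Ibsp led cluster 10. Cluster 11 held barcodes of few UMIs (medians of 1117.5 and 1376) led by muscle genes, with Myl1 at 2998 CPM in the untreated library and 1 UMI in the TNFa library, and Tnnc2 at 1085 CPM and 0 UMIs. Clusters 3 and 4 hold only 158 and 225 TNFa cells, against 1405 and 1240 untreated cells, so that their ratios describe few TNFa cells. Cluster 2, led by Cxcl13, Lcn2, Mmp3, Saa3 and Nos2, held 26.0% of TNFa cells but only 44 untreated cells, and was not compared. With TNFa it had the highest level among 9 classes of most of the 15 highest genes, such as Ccl5 (67755 CPM), Saa3 (30217) and Mmp3 (5729). Cxcl10, Cxcl9, Ccl20, Rsad2, H2-Q6 and AW112010 were highest in other classes. The main clustering did not leave out genes over 2-fold different. High levels of the genes that lead cluster 2, Saa3 and Mmp3 among them, may therefore follow from how it was formed.

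**Figure D2:**
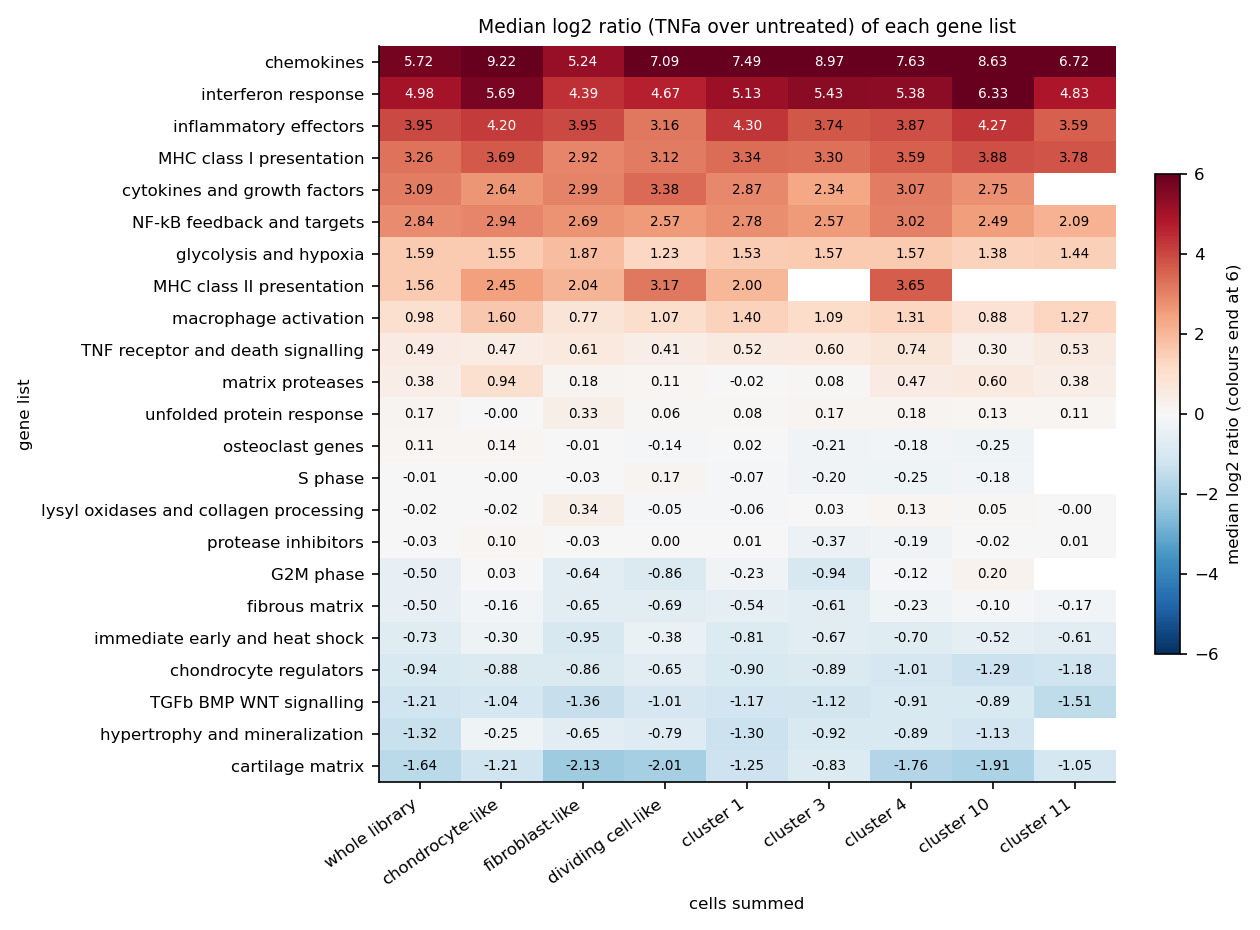
Median log2 ratio, TNFa over untreated, of each of the 23 gene lists (rows) in the whole libraries and within each of 8 classes or clusters (columns), blank with fewer than 5 measured members. The NF-kB row runs from 2.09 to 3.02, and the whole-library medians of S phase, lysyl oxidases and protease inhibitors, just below 0, lie above 0 with trimmed means.

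Ccl5, Cxcl10 and Cxcl9 were among the 5 highest ratios in both chondrocyte-like and fibroblast-like cells, and other genes differed between them in the size of the ratio. Mmp13 had 36 UMIs in untreated and 15847 UMIs (801 CPM) in TNFa chondrocyte-like cells, a ratio of 534 (386 to 763). In fibroblast-like cells it was at 5.39 and 73.8 CPM, a ratio of 13.7 (11.4 to 16.5). The difference of the log2 ratios was 5.27 (4.76 to 5.87). It was 0.32 with cluster 10, which carries 11 of 15 chondrocyte markers and most of the untreated Mmp13 UMIs of both, counted as chondrocyte-like, an alternative chosen after seeing the data. Mmp13 was then at 88.4 and 1501 CPM, a ratio of 17.0, so that the size of this difference depends on leaving cluster 10 out of the class. Lcn2 was at 18.0 and 3221 CPM in chondrocyte-like and at 33.4 and 954 CPM in fibroblast-like cells, a difference of 2.64 (2.48 to 2.82), or 2.67 with cluster 10. Cxcl1 reached similar levels in both, 818 and 780 CPM, from untreated levels of 1.58 and 20.6 CPM, a difference of 3.75. Cfb and Icam1 also had higher ratios in chondrocyte-like cells, with differences of 3.50 and 2.76. In the main cluster of each class, Cfb with TNFa was at 367 CPM in chondrocyte-like and 683 CPM in fibroblast-like cells. There Icam1 was at 673 and 325 CPM. Adamts5 was at 23.3 and 94.3 CPM in chondrocyte-like cells and at 510 and 578 CPM in fibroblast-like cells.

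Other genes had the higher ratio in fibroblast-like cells. Ptgs2, which makes prostaglandins, was at 5.90 and 91.2 CPM there and at 4.17 and 19.1 CPM in chondrocyte-like cells, a difference of -1.76 (-2.15 to -1.35). Prg4 was at 14.5 and 58.4 CPM in fibroblast-like and at 13.5 and 20.1 CPM in chondrocyte-like cells. Clustered without genes over 2-fold different, its log2 ratios were 1.19 and 0.91, closer than the 2.01 and 0.58 here. The level of Il6 with TNFa was 34.4 CPM in fibroblast-like and 5.36 CPM in chondrocyte-like cells, but its ratios were 14.5 and 21.4, a difference of 0.47 (-0.53 to 2.11). Nos2 had 0 UMIs in the untreated cells of both classes. It was at least 1703-fold higher in TNFa chondrocyte-like cells and at least 945-fold higher in fibroblast-like cells. Among the lowest ratios, Lgr5 was at 345 and 12.6 CPM and Sema3a, a guidance factor, at 148 and 7.36 CPM in fibroblast-like cells. Lgr5 is among the 10 genes that lead cluster 5, which holds most of the untreated fibroblast-like cells, and not among those of cluster 7, which holds most of the TNFa ones. Cluster 7 correlated best with untreated cluster 5 (0.674) and next with untreated cluster 9 (0.456). Neither this fall nor the other differences given for fibroblast-like cells are thus shown to lie within the same cells. Gdf10, a member of the BMP family, was at 176 and 7.13 CPM and G0s2 at 416 and 12.9 CPM in chondrocyte-like cells.

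Saa3 had a ratio of 14514 in chondrocyte-like and of 368 in fibroblast-like cells, a difference of 5.26. Of the untreated Saa3 UMIs of fibroblast-like cells, 92.6% came from the 83 cells of cluster 7. With each class reduced to its main cluster, an alternative chosen after seeing the data, the Saa3 difference was 1.56, that of Ccl5 turned from 1.71 to -1.05, that of Cxcl10 fell from 2.26 to -0.01 and that of Cxcl2 from -1.27 (-4.05 to 0.73, with no settled direction) to -1.97, while those of Mmp13, Lcn2 and Icam1 were 5.39, 2.60 and 2.84. Untreated UMIs in these main clusters, chondrocyte-like and fibroblast-like, were 9 and 4 for Ccl5, 2 and 1 for Cxcl10 and 5 and 1 for Cxcl2. No interval was computed for the reduced values, so the directions for Ccl5, Cxcl10 and Cxcl2 are not settled.

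**Figure D3:**
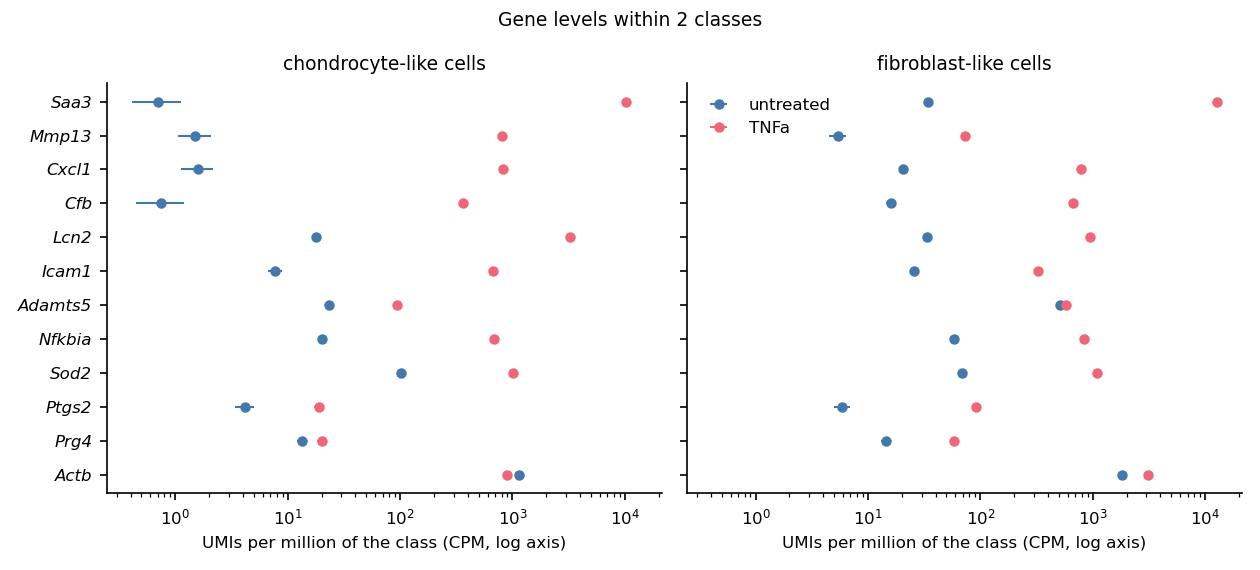
Level of 12 genes in chondrocyte-like and fibroblast-like cells of the untreated and TNFa libraries, in CPM of the class on a log axis, with exact Poisson 95% intervals as bars. Mmp13 reaches 801 CPM in TNFa chondrocyte-like cells and 73.8 CPM in TNFa fibroblast-like cells.

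Over gene lists, the interferon-response median was 5.69 in chondrocyte-like and 4.39 in fibroblast-like cells, a difference of 1.30 (1.03 to 1.47). With each class reduced to its main cluster, Gbp2 was at 0.127 and 269 CPM in chondrocyte-like and at 6.45 and 761 CPM in fibroblast-like cells. Gbp2, Gbp3, Gbp5, Rsad2, Psmb8, Psmb9, H2-Q4 and H2-K1, named from this and the MHC class I list, all had the higher TNFa level in fibroblast-like cells there. Rsad2 also had the higher log2 ratio in fibroblast-like cells, 9.30 against 8.22, and the others had the higher ratio in chondrocyte-like cells. For those others a higher ratio is thus not a higher level. Matrix proteases differed by 0.74 (0.58 to 0.85) over 20 members, 18 of which had the higher ratio in chondrocyte-like cells, or by 0.50 with cluster 10 counted among these. MHC class I presentation differed by 0.77 and the NF-kB list by 0.26 (0.11 to 0.42), or 0.48 with each library clustered on its own. Of the 22 NF-kB members, 15 had the higher ratio in chondrocyte-like cells and 7 in fibroblast-like cells. The median of their gene differences was 0.28, with an interval of -0.003 to 1.08 from resampling the members, which includes 0. The unfolded protein response list had a difference of -0.34, with the higher ratio in fibroblast-like cells for 16 of 18 members. Actb was at 1143 and 891 CPM in chondrocyte-like and at 1822 and 3113 CPM in fibroblast-like cells, but its log2 ratio in chondrocyte-like cells was 0.0171 with each library clustered on its own. The medians of chemokines differed by 3.35, but the median over 15 members of the gene differences was 0.38. Cartilage matrix differed by 0.94 (0.70 to 1.06), in a list whose genes named the chondrocyte-like class, and by -0.22 with each library clustered on its own, so that no direction is settled. These intervals do not cover differences between cultures.

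Cluster 10, with 311 untreated and 217 TNFa cells, carried 11 of 15 chondrocyte markers, against 2 for the next type, but was left unnamed by the naming thresholds. It had the highest Mmp13 levels, 434 and 4354 CPM, a ratio of 10.0, below that of fibroblast-like cells, though Mmp13 is among the genes that lead it. Mmp3 was at 4.97 and 3754 CPM there and Col2a1 at 7413 and 1973 CPM. In the dividing cell-like class Saa3 had 1 untreated UMI and stood at 6948 CPM with TNFa. Col2a1 was at 1637 and 437 CPM there.

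The third comparison asks whether the shares of the classes differed. Because genes that lead the clusters differ between the libraries, shares are given from the clustering without genes over 2-fold different. Chondrocyte-like cells were 19.9% of untreated cells (19.1 to 20.8) and 19.2% of TNFa cells (18.2 to 20.2). Fibroblast-like cells were 16.2% (15.4 to 17.1) and 17.4% (16.4 to 18.3), and dividing cell-like cells 2.79% (2.44 to 3.18) and 3.02% (2.61 to 3.47). Clusters are numbered anew in this clustering, and those that the naming thresholds left unnamed held 13.3% and 16.2% (cluster 1), 4.66% and 20.6% (cluster 2), 15.1% and 6.10% (cluster 4), 13.3% and 7.61% (cluster 5), 6.66% and 0.176% (cluster 9), 2.48% and 4.41% (cluster 10), 2.95% and 2.86% (cluster 11), 1.26% and 0.943% (cluster 13) and 0.527% and 0.655% (cluster 14). A cluster held mostly by 1 library may be a state of that library and not a cell type. Chondrocyte-like shares moved with the clustering, to 22.9% and 31.6% with each library clustered on its own, so that no difference in them is settled. The fibroblast-like difference is not settled either, at 9.46 points without centring by library, 5.18 at resolution 1.4 and 3.39 with each library clustered on its own. Adipocyte-like, Schwann-like and macrophage-like cells were each under 0.5% of either library.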

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

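The tests of free RNA, doublets, class shares and clusters 2 and 3 were chosen after the clusters had been seen. The outcome each explanation needs was written down before the ratios given here were computed. Whole-library ratios had already been used in clustering, to leave out genes over 2-fold different. Trimmed means and the other clusterings were chosen before the data were examined. The tests of which cells carry each gene, of the amounts in them and of the cartilage list within chondrocyte-like cells were chosen after the results had been seen. Actb had a ratio of 0.780 (0.765 to 0.795) in chondrocyte-like cells and of 1.71 (1.69 to 1.73) in fibroblast-like cells. It drew attention because the ratios of these classes lie on opposite sides of 1, and the difference between the classes was not tested, as each is 1 sample. With each library clustered on its own, the log2 ratio in chondrocyte-like cells was 0.0171 in place of -0.36, so that the lower level there is not settled.

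The genes highest in the TNFa library were higher in it in every class compared. Free RNA from responding cells would keep these genes in 1 ratio to each other in every class, but the median over the 15 genes of the SD over 9 classes of their relative log2 level was 0.745, above the 0.5 set beforehand as too much for free RNA alone. These classes include cluster 11, and cluster 2, which is led by Cxcl13, Mmp3, Saa3, Nos2 and Il13ra2 of the 15. The SD therefore does not show that any given class holds more than free RNA. Taking out the cells of highest doublet score left the median log2 ratio of the 15 genes at 11.02 against 11.01, which decides nothing, since doublets leave the ratio of the whole libraries as it is. Over the 15 genes, the lowest share over 8 classes of cells with a UMI of the gene had a median of 58.3%. These classes leave out cluster 11. For 9 genes this share was above what 12% of doublets and free RNA at its bound (cluster 11 taken as free RNA) give together. The margin was small for Ccl5, Ccl2, Cxcl10 and Ccl20. The share was not above it for Cxcl9, Saa3, Mmp3, Cxcl13, Il13ra2 and AW112010. It thus goes against doublets as the source of the whole set and does not decide for these 10 genes. For Ccl5, Ccl2 and Cxcl10, free RNA at its bound alone gives 99.99%, 96.97% and 89.51% of cells. Their shares therefore do not tell doublets from free RNA. In its class of lowest value, a median of 25.9% of a gene's UMIs lay outside the 12% of cells that hold most of them. This lies between the 20% and 50% set as bounds. Ccl5 (55.9%), Cxcl10 (57.6%), Ccl2 (66.3%) and H2-Q6 (54.7%) stood above 50%, and 6 genes, among them sparse ones such as Cxcl13, under 20%. In those classes free RNA at its bound would give a median of 6.93% of a gene's UMIs, and at most 27.35% (Cxcl13). A part from doublets thus stays open, and so does a part from free RNA, of that size if cluster 11 is free RNA. The difference between the libraries cannot be told apart from any other difference between the cultures. A response to TNFa is the biological explanation that the design names, and it was not tested.

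Cartilage matrix genes were lower in the TNFa library. If a few very high genes took up the counts, scaling by trimmed means would bring the list median near 0, but it was -1.37 against -1.64. With the untreated class shares given to both libraries the median was -1.59, which decides nothing, since those shares were 19.9% and 19.2% already. If fewer chondrocyte-like cells were the reason, the list would not differ within them, but its median there was -1.21 (-1.27 to -1.13), and this and the trimmed means go against both explanations as the whole reason for the pattern. The class is mostly cluster 6 in the untreated and cluster 8 in the TNFa library. TNFa cluster 8 correlated best with untreated cluster 6 (0.69) and next with untreated cluster 10 (0.45). A shift in which cells make up the class is therefore not excluded. Loss of cartilage transcripts with time in culture or without serum stays open, since the labels do not say whether both cultures were kept alike, and so does a response to TNFa.

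Cluster 2 held 44 untreated and 1628 TNFa cells, and cluster 3 held 1405 and 158. A candidate explanation is that they hold 1 kind of cell with and without TNFa. Over 3061 genes within 2-fold between the libraries, which are not independent replicates, the profile of cluster 2 correlated best with untreated cluster 3, at r of 0.53, with untreated cluster 6 next at 0.36. Against a simple reading, the 158 TNFa cells of cluster 3 itself correlated with untreated cluster 3 at 0.67. A cluster of cells mostly from 1 library may be a property of that library, and this stays open.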

How the results depend on the processing

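The 119 named genes of the whole libraries gave 1071 values under 9 other settings, of which 755 stayed within counting error, 312 moved beyond it and 4 changed direction. A change of direction is counted only where the main value's interval excluded 0. Of 276 list medians 175 stayed, 97 moved and 4, all of protease inhibitors, changed direction. Within classes, 372 of 512 gene ratios, 458 of 575 list medians and 113 of 138 list differences stayed, and 1, 4 and 1 changed direction. No cell filter, keeping the predicted doublet and leaving out cluster 11 moved 0 whole-library genes and lists. Leaving out the cells of highest doublet score, cluster 11, or the smaller clusters of a class, and counting cluster 10 as chondrocyte-like, were chosen after seeing the data, and the other settings were planned. The shift added to every log2 ratio was 0.16 for centring on the median gene and 0.27 for trimmed means. The cause of the other moves was not tested. Which moves are given as values below was settled after a first set of moves had been seen.

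For the whole libraries, the NF-kB list median of 2.84 was 3.00 with centring, 3.10 with trimmed means, 2.75 with cells thinned to 5000 UMIs and 1.86 with 10 CPM added. Chemokines (5.72) gave 5.99 with trimmed means, 5.27 as a mean of per-cell CPM, 5.98 thinned, 6.58 with members of 200 UMIs or more and 2.48 with 10 CPM added. Inflammatory effectors (3.95) gave 4.11 with centring, 4.21 with trimmed means, 3.83 thinned and 2.20 with 10 CPM added. Cartilage matrix (-1.64) gave -1.47 with centring, -1.37 with trimmed means, -1.44 as a mean of per-cell CPM, -1.41 thinned, -1.31 with 10 CPM added and -1.54 with classes weighted alike. These 4 lists kept their direction under all settings run. Protease inhibitors (-0.03) turned to 0.13 with centring, 0.23 with trimmed means, 0.14 thinned and 0.0420 with 10 CPM added. S phase (-0.01) and lysyl oxidases (-0.02), with intervals that include 0, stood at 0.15 and 0.14 with centring and at 0.26 and 0.25 with trimmed means, S phase at -0.12 thinned and with classes weighted alike, and lysyl oxidases at 0.0304 with the latter. Slbp turned to 0.0138 and Top2a to 0.0752 with trimmed means, and Ctsk to 0.00963 with centring and 0.12 with trimmed means. Thinning left out 327 untreated and 377 TNFa cells, and the median genes per cell were 2160 and 2074, against 4317 and 4656 unthinned.

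Shares here start from the main clustering, where chondrocyte-like cells were 17.7% of untreated and 17.6% of TNFa cells. Their TNFa minus untreated difference, -0.09 points, was -0.78 in the clustering without genes over 2-fold different, used above. It was 10.9 at resolution 0.4, 3.07 at resolution 1.4, 4.76 without centring by library, 8.63 with each library on its own, -2.52 with doublets kept and 4.18 with the stricter filter. Fibroblast-like cells were 18.4% and 19.3% in the main clustering. Their difference, 0.89 points, was 1.14 without genes over 2-fold different, 5.18 at resolution 1.4, 9.46 without centring by library and 3.39 with each library on its own. Keeping doublets adds 1 cell, so the chondrocyte-like share depends on small changes of the clustering. The dividing cell-like share stayed within counting error under all 8 settings.

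Within fibroblast-like cells the NF-kB median of 2.69 was 2.81 with centring and 2.42 with each library on its own. Its difference between classes, 0.26, was 0.48 with each library on its own. That of matrix proteases, 0.74, was 0.50 with cluster 10 as chondrocyte-like. The cartilage matrix difference, 0.94, was 0.67 without genes over 2-fold different and turned to -0.22 with each library on its own. With centring, 4 list medians within classes whose intervals excluded 0 turned, besides others whose intervals include 0: protease inhibitors to 0.0833 in fibroblast-like cells, fibrous matrix to 0.0836 in cluster 10 and 0.105 in cluster 11, and S phase to 0.00621 in cluster 10. Actb in chondrocyte-like cells turned to 0.0171 with each library on its own.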

Other observations

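No test was run for this part, and Marco and Calcr were chosen after their values were seen. The macrophage-like class had 16 untreated and 20 TNFa cells. Those 20 cells held 96.8% of the TNFa library's UMIs of Marco, a scavenger receptor of macrophages, and 65.2% of its Tnf UMIs. Tnf stood there at 318 CPM (275 to 367), against 39.9 CPM (19.9 to 71.4) in the 16 untreated cells. Calcr, the calcitonin receptor, had 0 untreated and 594 TNFa UMIs, of which 50.2% lay in fibroblast-like cells and 28.6% in cluster 2. In the 18 TNFa adipocyte-like cells it stood at 108 CPM (83.5 to 138), and the macrophage-like cells had 0 Calcr UMIs.

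Cluster 9, led by Clec3b, Ly6a, Creb5 and Cd55, held 527 untreated cells and 16 TNFa cells. Clustering without genes over 2-fold different put 443 of these untreated cells again in a cluster of 518, with 11 TNFa cells. Over 3061 genes within 2-fold between the libraries, TNFa cluster 7 correlated best with untreated cluster 5, at r of 0.67, and next with untreated cluster 9, at 0.46. No class name was given to cluster 9, which had 3 fibroblast and 3 superficial chondrocyte markers.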
